A study of Mus musculus with 4 samples.

How the data were processed

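Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered, after 5 days of differentiation. Mef2Da1 and Mef2Da2 are splice isoforms of the transcription factor Mef2D, and each was precipitated with its own antibody. The controls were the same antibodies blocked with peptide. This gave 4 samples in 4 groups (Mef2Da1, Mef2Da2, Mef2Da1-BLOCK and Mef2Da2-BLOCK) with 1 library each, so no difference between groups could be set against a spread between replicates. Groups were taken from the antibody named in the sample labels.

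The authors deposited 1 peak list per isoform and 1 combined table of regions for all 4 libraries. BWA 0.5.9 and the mouse build mm9 are named in the submitters' processing notes; the peak caller, its filters, the number of reads per library and the way in which the combined regions were chosen are not given in the sources used here. In the deposited files the signal of a peak or region is a coverage height, in whole numbers and not scaled to depth. It was read as the maximal height and not as a count of reads, because wherever several listed peaks lay in 1 combined region the height in the table equalled the highest of them (158 of 158 regions for Mef2Da1 and 193 of 193 for Mef2Da2). The deposited lists also give a −log10 p for each peak, none below 6, and the combined table gives one for each region and library. For the blocked libraries this column of the deposited table was treated as a score, since 1 region of Mef2Da1-BLOCK and 9 of Mef2Da2-BLOCK had a value below 0. Columns of the combined table were matched to samples through the names of the samples' own peak lists, because the titles do not use the table's column names; over regions with a listed peak, the isoform's height equalled that of the highest peak in its own list in 8252 of 8253 regions for Mef2Da1 and in 9215 of 9215 for Mef2Da2. Heights and −log10 p are the authors' values. Depth was unknown, so no Poisson interval was given for any height.

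Peaks of both lists were compared by position, with 1 shared bp as the main rule. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent. The overlap was set against 1000 shuffles of peak positions within each chromosome, with a one-sided p. Median −log10 p was compared between overlapping and non-overlapping peaks within each list by a two-sided permutation test with 100000 resamples, and Benjamini-Hochberg adjustment covered the 2 lists. These tests compare lists of peaks, not replicated conditions. The combined regions were classed by whether they contained a listed peak of both isoforms, of 1 isoform or of neither. Ratios of heights used a pseudocount of 1. Mef2Da1 was compared with Mef2Da2 after scaling each library to its total height over the table. The plan for the ratio of an isoform to its blocked control named no scaling for the main value and listed total and median scaling; the unscaled ratio was made the main value after the files had been examined, and both scaled values are printed beside it.

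The comparisons, the 1 bp rule and most alternatives were chosen before the data were examined. The breakdown by peak strength, the −log10 p levels of 3, 6, 6.5 and 10, the blocked score of 5, the 4-fold counts, the regions with the largest ratio, the scaling to blocked totals, the scalings within classes, the overlap over peaks in combined regions alone and several tests of explanations were chosen afterwards. Overlap code was tested on simulated lists: with 0%, 30% and 60% of peaks planted as shared, it recovered 0.323%, 30.2% and 60.1%. For 2 classes of simulated values drawn from the same distribution, 1000 values in all, the permutation test gave 4.5% false positives. Classes with equal medians but unlike spreads were not simulated. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

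No genome or annotation of the build mm9 was used here. The gene table at hand was of assembly GRCm38.p6, and 7 chromosomes had a combined region beyond its last gene, so regions were not assigned to genes. The planned counts of genes bound by both isoforms, promoter shares, 11 fixed gene lists and the MEF2 motif were therefore not run. In their place, as planned for this case, the 5 peaks with the highest −log10 p in each class were named by coordinates (for peaks of both isoforms, by the sum of ranks in both lists). Peak coordinates are 1-based; those of combined regions are printed as given in the table.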

Results

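ChIP-seq signal of the Mef2D splice isoforms Mef2Da1 and Mef2Da2 was compared in C2C12 myotubes (a mouse muscle cell line) at day 5 of differentiation, with a peptide-blocked antibody control for each isoform. There were 4 groups with 1 library each. No value below has a replicate error, and no test compares replicated conditions. The number of reads per library was unknown.

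The Mef2Da1 list held 8872 peaks and the Mef2Da2 list 10105 peaks, spread over the 19 autosomes. Mef2Da1 peaks had a median width of 430 bp (quartiles 346 and 573) and a median coverage height of 57 (range 42 to 808). Mef2Da2 peaks were narrower, with a median of 346 bp (quartiles 291 and 423), and had a median height of 56 (range 34 to 753). The median of the authors' −log10 p was 8.10 for Mef2Da1 and 9.21 for Mef2Da2, and the lowest value was 6.01 in both lists. The same −log10 p stood for unlike heights. In combined regions with a height of 40 it was 4.35 to 5.70 for Mef2Da1 and 6.01 to 7.29 for Mef2Da2. A cut in −log10 p thus admitted lower heights for Mef2Da2, which bears on list lengths and on the peaks found in 1 list only. Peaks were densest on chromosome 15, with 7.06 Mef2Da1 peaks and 7.73 Mef2Da2 peaks per Mb, against 3.70 and 4.22 over all chromosomes. Chromosome 11 followed, with 5.52 and 5.50 peaks per Mb.

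The first comparison addressed whether the isoforms occupied the same places in the genome. Of the Mef2Da1 peaks, 5467 of 8872 overlapped a Mef2Da2 peak (61.6%, 95% interval 60.6 to 62.6). In the other direction, 5514 of 10105 Mef2Da2 peaks overlapped a Mef2Da1 peak (54.6%, 95% interval 53.6 to 55.5). Overlapping peaks were nearly centred on each other, with a median distance of 29.5 bp between midpoints over 5467 pairs, and the Mef2Da1 peak was the wider one in 73.1% of pairs. Across these pairs the −log10 p values of the isoforms had a Spearman correlation of 0.55 and a Pearson correlation of 0.64, across peaks that are not independent replicates. Shuffled positions gave a mean overlap of 0.387% for Mef2Da1 and 0.341% for Mef2Da2, and no shuffle exceeded 0.575% and 0.554% (one-sided permutation p = 0.001 for each, the smallest that 1000 shuffles can give). With Mef2Da1 peaks moved by only 10 to 100 kb, the overlap by chance was 1.13%. Both ways of moving peaks drew positions without regard to where a peak of any library could arise. They set the overlap against random placement alone and cannot tell shared occupancy from other reasons for peaks at the same places.

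Stronger peaks were shared more often. The share of Mef2Da1 peaks with an overlapping Mef2Da2 peak was 30.9% (95% interval 27.8 to 34.01) in the weakest 10% of the list by −log10 p and 98.8% (97.8 to 99.4) in the strongest 10%. For Mef2Da2 it was 29.4% (26.6 to 32.3) in the weakest 10% and 85.4% (83.1 to 87.6) in the strongest. In the Mef2Da1 list the median −log10 p was 9.44 for overlapping and 7.00 for non-overlapping peaks, a difference of 2.44. In the Mef2Da2 list it was 11.1 and 7.89, a difference of 3.26. The two-sided permutation test over peaks gave p = 1e-05 in each list, the smallest that 100000 resamples can give, and 1e-05 after Benjamini-Hochberg adjustment over the 2 lists.

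**Figure D1:**
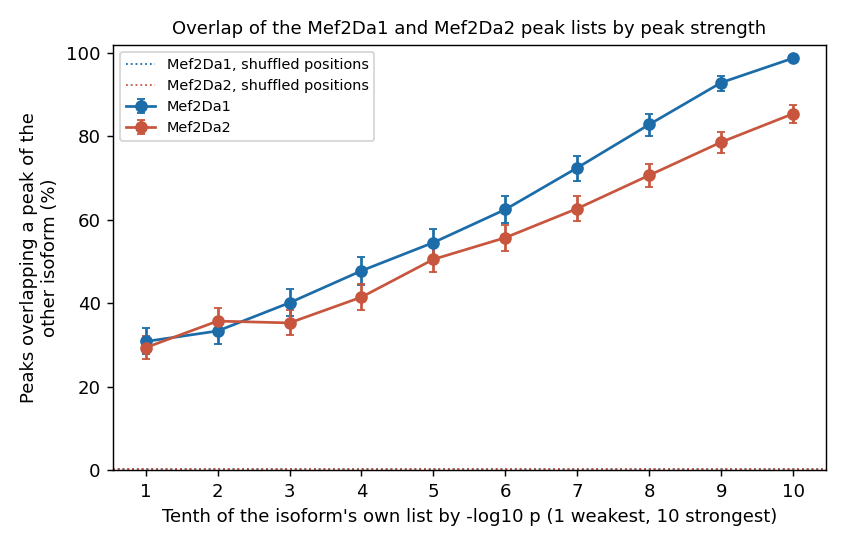
Share of peaks (%) overlapping a peak of the other isoform, with each isoform's list divided into 10 equal parts from the weakest (1) to the strongest (10) −log10 p; points are shares, bars exact 95% intervals and dotted lines the mean share with shuffled positions. The share was 30.9% and 29.4% in the weakest part for Mef2Da1 and Mef2Da2, and 98.8% and 85.4% in the strongest.

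The 5 strongest overlapping peaks, by the sum of their ranks in both lists, were high in both isoforms. Coordinates are of the build mm9 and of the Mef2Da1 peak, and no gene annotation of that build was used here. The first was at chromosome 19, 4992440 to 4993596, where Mef2Da1 reached a height of 808 and Mef2Da2 of 753, against 18 and 14 in their blocked controls. Next came chromosome 10, 85775806 to 85776966, with heights of 583 and 446 against 30 and 22. At chromosome 17, 15598789 to 15599751, the heights were 374 and 441 against 27 and 17. The peak at chromosome 4, 47616562 to 47617338, had heights of 316 and 501 against 16 and 15. The peak at chromosome 10, 80403079 to 80404373, had heights of 405 and 369 against 33 and 19.

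The strongest Mef2Da1 peaks without an overlapping Mef2Da2 peak were lower. At chromosome 2, 56976375 to 56976784, Mef2Da1 had a height of 167 and Mef2Da2 of 32, against 19 and 5 in their blocked controls. At chromosome 8, 86108667 to 86109119, the heights were 159 and 22 against 36 and 22. Chromosome 8, 47556167 to 47557044, had 134 and 39 against 19 and 21. Chromosome 16, 17208863 to 17209457, had 127 and 24 against 28 and 17. At chromosome 9, 63550132 to 63551023, Mef2Da1 had a height of 129 and Mef2Da2 a height of 172 with no listed peak. The blocked controls stood at 30 and 34 there.

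Among the strongest Mef2Da2 peaks without an overlapping Mef2Da1 peak, the one at chromosome 2, 125429461 to 125430225, had a Mef2Da2 height of 474 and a Mef2Da1 height of 39, with 12 and 25 in the respective blocked controls. By contrast, Mef2Da1 reached 248 without a listed peak at chromosome 15, 79073329 to 79074417, where Mef2Da2 had 386. The blocked controls of Mef2Da1 and Mef2Da2 stood at 44 and 26 there, with a Mef2Da1-BLOCK score of 6.03. At chromosome 1, 94683688 to 94684210, Mef2Da1 reached 350 and Mef2Da2 342, against 38 and 33, with a Mef2Da1-BLOCK score of 5.12. The peaks at chromosome 4, 42966519 to 42967112, and chromosome 8, 97733753 to 97734310, had Mef2Da2 heights of 402 and 330 and did not lie in a combined region, so the other libraries could not be read there.

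**Figure D2:**
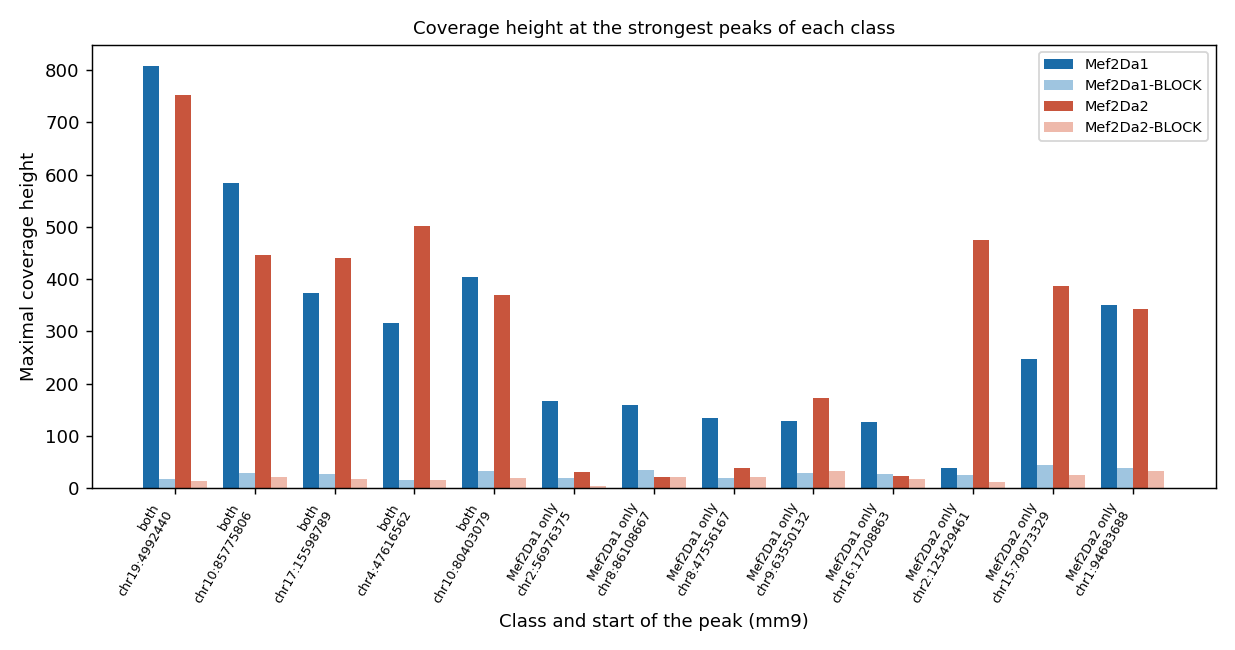
Maximal coverage height (vertical axis, unscaled) of the 4 libraries at the strongest peaks of each class that lay in a combined region, labelled by chromosome and start in mm9; each bar is 1 library. Both isoforms were high at the 5 shared peaks. Mef2Da1 stood at 248 and 350 at 2 peaks listed for Mef2Da2 alone, against 44 and 38 in its blocked control.

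The second comparison set each isoform against its peptide-blocked control over the 19749 combined regions. Of these, 5247 contained peaks of both isoforms, 3006 a Mef2Da1 peak only, 3968 a Mef2Da2 peak only and 7528 no listed peak. In regions with peaks of both, the median height was 65 for Mef2Da1 and 67 for Mef2Da2, against 19 and 13 in the blocked controls. In regions with a Mef2Da1 peak only, it was 51 for Mef2Da1 against 22 in its blocked control, and in regions with a Mef2Da2 peak only it was 49 for Mef2Da2 against 10. A −log10 p of 6 or more was reached in 8003 regions by Mef2Da1 and 9109 by Mef2Da2, and a score of 6 or more in 34 and 0 regions by their blocked controls. Without scaling, 85.2% of the regions with a Mef2Da1 peak were at least 2-fold above the blocked control, with a median log2 ratio of 1.54, and 97.8% of those with a Mef2Da2 peak, with a median of 2.42. For Mef2Da1 the share was 92.6% in regions with peaks of both and 72.4% in regions with a Mef2Da1 peak only. For Mef2Da2 it was 97.5% in regions with peaks of both and 98.2% in regions with a Mef2Da2 peak only. Over all 19749 regions the shares were 64.7% and 74.96%, and in regions with no listed peak 46.8% and 60.8%.

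These shares depended on scaling, and the unscaled form was chosen after the files had been examined. Scaled to the total height over the table, the shares over regions with a listed peak of the isoform were 15.1% and 27.7%. Scaled to the median ratio they were 19.9% and 39.99%. Both scalings set the libraries equal over regions chosen for signal. The unscaled shares carry a like limit. They were read in regions with a listed peak of the isoform itself, not in regions chosen through the blocked control. A height above the blocked control there can follow in part from that choice and from unknown depth. None of these shares is therefore a measure of enrichment free of selection.

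**Figure D3:**
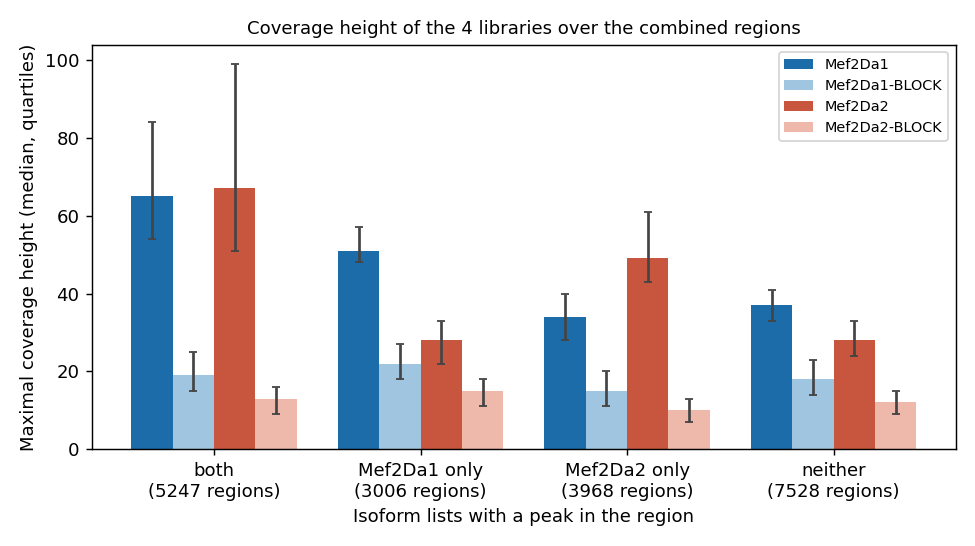
Maximal coverage height (median with quartiles, unscaled) of the 4 libraries over the combined regions, by the isoform lists with a peak in the region. In the 5247 regions with peaks of both isoforms the medians were 65 and 67, against 19 and 13 in the blocked controls.

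The third comparison set Mef2Da1 against Mef2Da2 over the same regions. After scaling to the total, 83.3% of regions were within 2-fold, Mef2Da1 was over 2-fold higher in 1900 regions (9.62%) and Mef2Da2 in 1389 (7.03%). In regions with peaks of both isoforms, 93.5% were within 2-fold. Where 1 isoform alone had a listed peak, the ratio stayed within 2-fold in 60.0% of regions (Mef2Da1 only) and 72.7% (Mef2Da2 only). These class shares changed with the scaling: they were 71.7% and 63.4% scaled to the median ratio, and 91.1% and 34.1% scaled to the blocked controls' totals, where regions with peaks of both fell to 77.1%. Over all regions the heights of the isoforms had a Spearman correlation of 0.31, and their log2 heights a Pearson correlation of 0.46. The pooled Spearman value mixed 0.58 in regions with peaks of both with −0.29 in regions with no listed peak. It was 0.15 in regions with a Mef2Da1 peak only and 0.06 in those with a Mef2Da2 peak only. A negative value in regions with no listed peak can follow from selection alone. There the −log10 p values of both isoforms summed to at least 6.06, while neither isoform had a listed peak. The heights of Mef2Da1 and Mef2Da2 had correlations of 0.32 and −0.10 with their own blocked controls. The side with more regions changed with the scaling: scaled to the median ratio, Mef2Da1 was higher in 6.13% and Mef2Da2 in 9.71%, and scaled to the blocked controls' totals in 1.60% and 20.7%. Total scaling left a median log2 ratio of 0.17.

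Signal of the other isoform was also read in regions with a peak of 1 isoform only. Mef2Da2 had a −log10 p of 3 or more in 74.3% (95% interval 72.6 to 75.8) of the regions with a Mef2Da1 peak only, against 6.22% (5.38 to 7.14) for its blocked control. Mef2Da1 had one in 76.4% (75.01 to 77.7) of the regions with a Mef2Da2 peak only, against 9.83% (8.92 to 10.8) for its blocked control. In the 7528 regions with no listed peak, which were likewise without a peak of that isoform and lay in a table restricted to regions with joint signal, values were similar: the median −log10 p of Mef2Da2 was 4.13 against 4.00 in the regions with a Mef2Da1 peak only, and that of Mef2Da1 was 4.40 against 4.09 in those with a Mef2Da2 peak only. By height and without scaling, the median log2 ratio of Mef2Da2 to its blocked control was 0.82 in regions with a Mef2Da1 peak only. It was 1.15 in regions with no listed peak. For Mef2Da1 it was 1.05 in regions with a Mef2Da2 peak only and 0.94 in regions with no listed peak. Mef2Da2 was not above its blocked control in 268 of 3006 and 233 of 7528 of these regions, and Mef2Da1 in 83 of 3968 and 60 of 7528. In the isoform-only regions the ratios of Mef2Da2 and Mef2Da1 were −1.13 and −0.32 scaled to the total. Scaled to the median ratio they were −0.81 and −0.15. Both scalings centre the libraries on regions chosen for signal. The table held no region in which the −log10 p values of both isoforms summed to less than 6.06. Regions without signal of either isoform could therefore not serve as a baseline. Depth also limits the contrast in −log10 p with the blocked controls, since a level of 3 may not mean the same in each library. Summed over the combined regions, height was 973579 for Mef2Da1 and 377117 for Mef2Da1-BLOCK, and 955997 for Mef2Da2 and 247315 for Mef2Da2-BLOCK.

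**Figure D4:**
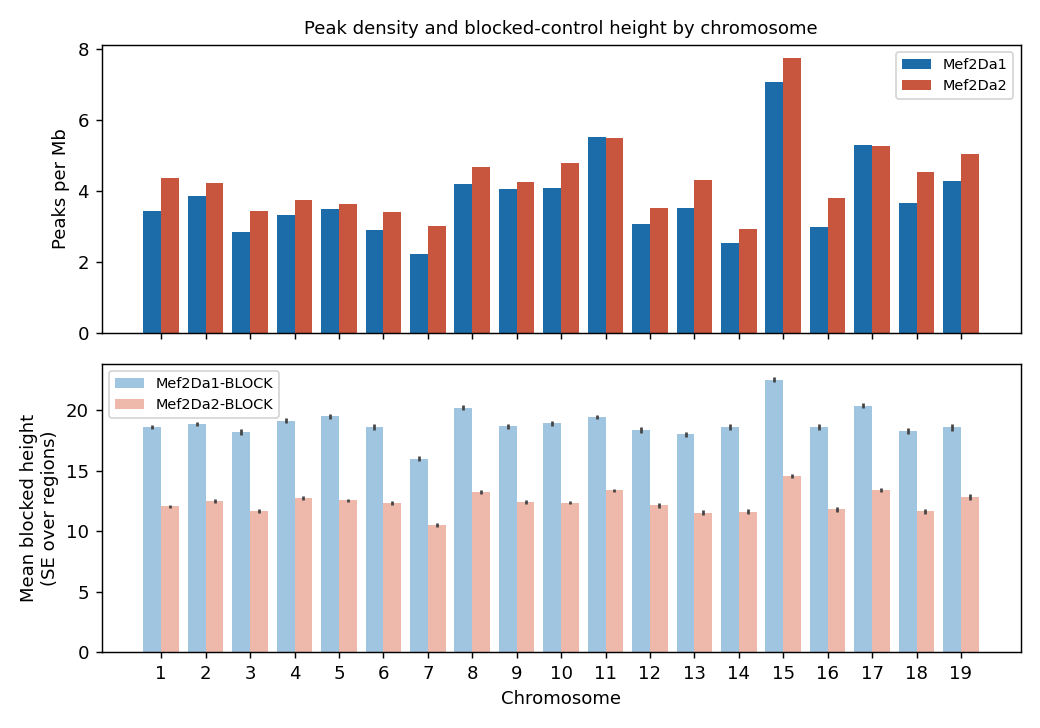
Peaks per Mb in each isoform's list (upper panel) and mean coverage height of the blocked controls over the combined regions, with the standard error over regions (lower panel), for the 19 autosomes. Chromosome 15 had the most peaks per Mb, 7.06 and 7.73, and the highest blocked mean heights.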

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

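The alternatives restricted to combined regions and the scaling to blocked totals were chosen after seeing the data; the unscaled isoform-to-control ratio was made the main value then too. The 51 alternative values were judged by 3 rules, so they are not 1 measure of stability: all 19 with a test stayed past its threshold, whatever the size of the share; of 6 counts of peaks, 4 stayed within 1.5 times the main count; and of 26 values with no test, 2 stayed within the bound set (for shares, the main share's 95% interval) and 24 moved. Between the isoforms, the side with more 2-fold regions changed with median scaling and with blocked totals. The overlap shares ranged from 57.6% to 81.9% for Mef2Da1 and from 50.6% to 70.6% for Mef2Da2 over the alternatives fixed beforehand and stayed above the shuffled share in each. Over the 8418 and 9418 peaks in a combined region alone, the overlap was 63.2% and 56.9%; counting the other isoform there as present at a −log10 p of 6 gave 63.5% and 57.9%, and at 3 gave 90.8% and 90.0%, a looser rule by construction. The difference between shared and other peaks kept its direction with widths (45 and 77 bp) and with the stricter overlap rule. Keeping only peaks at or above each list's median −log10 p left 4440 and 5108 peaks, by construction. The share of regions at least 2-fold above the blocked control was 15.1% and 27.7% scaled to the total, 19.9% and 39.99% scaled to the median ratio, and 78.7% and 96.2% with a pseudocount of 5; such scaling removes the general difference in height by construction. Mef2Da1 was over 2-fold above Mef2Da2 in 6.13% and the reverse held in 9.71% with median scaling, 7.08% and 6.11% with a pseudocount of 5, and 1.60% and 20.7% with blocked totals; which scaling is right was not tested. The filter at a summed height of 20 and the removal of other chromosomes took away nothing and test nothing. Results that need genes, promoters, gene lists or the MEF2 motif were not run, nor their alternatives, for lack of a reference of the same build. Unknown depth limits every comparison of heights or of −log10 p between libraries.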

Other observations

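Tests of the median and trimmed peak windows, of the 2 antibodies apart, of the other isoform below its threshold, of peaks removed by the blocked control and of p near the threshold were chosen only after the result was seen, as were the regions and counts in the next paragraphs, the random placement of peaks and the relation of blocked height to density; the tests of extra copies, merged clusters, weak peaks and background for both antibodies jointly were written before. The rule for the other isoform below its threshold was revised repeatedly after its values were seen, with its verdict changing between support and undecided.

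The largest differences between the isoforms had unlike shapes. The 3 regions with the largest ratio toward Mef2Da2, picked after their values were seen, had high Mef2Da2 signal: 474 against 39 for Mef2Da1 at chromosome 2, 125429442 to 125430290; 460 against 45 at chromosome 12, 87432133 to 87433175, where both isoforms had a listed peak; and 140 against 16 at chromosome 8, 33286661 to 33287040. The 3 toward Mef2Da1 had modest Mef2Da1 heights of 55, 62 and 51 and Mef2Da2 heights of 4, 5 and 4, at chromosome 3, 136362705 to 136362998, chromosome 4, 98872544 to 98872910, and chromosome 3, 58218559 to 58219100. There the Mef2Da2 blocked control stood at 5, 16 and 15. At least 4-fold differences were found in 78 regions toward Mef2Da1 and 152 toward Mef2Da2 with total scaling, 57 and 236 with median scaling, and 15 and 608 with blocked totals, so Mef2Da2 had more of them under each of these scalings, whereas the count of 2-fold differences changed sides.

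Of the strongest 10% of each list, 11 of 887 Mef2Da1 peaks and 147 of 1010 Mef2Da2 peaks lacked a peak of the other isoform. Of the latter, 119 lay in a combined region, and Mef2Da1 had a −log10 p of 6 or more in 21 of them, of 3 to 6 in 86 and below 3 in 12.

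Whether peaks of 1 isoform without a peak of the other reflect the threshold of the lists stays open. In such regions the other isoform's median −log10 p exceeded the median score of its own blocked control by 2.37 (Mef2Da2) and 2.60 (Mef2Da1). In regions with no listed peak it did so by 2.77 and 2.57. That class is no baseline, since the table held no region in which the −log10 p values of both isoforms summed to less than 6.06. A region without a listed peak then mostly needs signal of both to be in the table. The comparison with that class therefore cannot decide the question. By height the median log2 ratio to the blocked control in isoform-only regions was 0.82 (Mef2Da2) and 1.05 (Mef2Da1) unscaled. In regions with no listed peak it was 1.15 and 0.94. Under both scalings over the table, the ratio in isoform-only regions was below 0. Mef2Da2 was not above its blocked control in 268 of the 3006 regions with a Mef2Da1 peak only. Mef2Da1 was not above its own in 83 of the 3968 with a Mef2Da2 peak only. The table lacked regions without signal of either isoform, which could have served as a baseline. Of the combined regions with a peak of 1 isoform only, at most 6.28% had the other isoform at a −log10 p of 6 or more. Loss of a called peak of the other isoform thus accounts for few of these regions. Among the 1010 strongest Mef2Da2 peaks, 119 in a combined region lacked a Mef2Da1 peak, and Mef2Da1 reached that level at 21. Among the 887 strongest Mef2Da1 peaks, Mef2Da2 did so at 1 of 9 such peaks. The 454 Mef2Da1 and 687 Mef2Da2 peaks outside the combined regions could not be read, so loss was not tested there. Background shared with the blocked control gave a split answer: the planned joint test was undecided, because blocked height in isoform-only regions over that in regions of both was 1.16 for Mef2Da1, under the bound of 1.2, and 0.769 for Mef2Da2. Split by antibody after that result, the Mef2Da2 value of 0.769 went against the prediction of background, and the Mef2Da1 value was undecided. Over all combined regions, however, Mef2Da1 height rose with Mef2Da2-BLOCK height (Spearman correlation 0.28), whereas Mef2Da2 height did not (−0.10). Leaving out regions with a Mef2Da1 peak can therefore lower the blocked height by itself, and the split cannot decide on background for either antibody. True isoform-specific binding also stays open.

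Some regions passed a −log10 p of 6 without a listed peak, 481 of 8003 for Mef2Da1 and 177 of 9109 for Mef2Da2. The table's p differed from that of the lists, by up to 1.88 upward for Mef2Da1 and less for Mef2Da2 among listed peaks below 6.5, so p recomputed near the threshold does not account for 96 Mef2Da1 regions farther above 6 than that; for the other 385, with 57.7% under 6.5 against 33.5% of listed regions in the same range, it stays open. A candidate explanation for some is a filter on the blocked control: past 6.5, 93.0% of regions with a blocked score of 5 or more (106 of 114) had no listed peak, against 2.32% (153 of 6591) of the rest, a level of 5 chosen from these data. Of the 96 Mef2Da1 regions, 77 had such a score and 19 did not. Only 3 Mef2Da2 regions past 6.5 had a blocked score of 5 or more. Of these, 1 had no listed peak, against 28 of the other 8139 (0.344%). For Mef2Da2, recomputed p may account for most, with 83.6% under 6.5 and 5 farther above 6 than the listed peaks moved, and no biological explanation was tested.

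Chromosome 15 had more peaks per Mb than any other chromosome in both lists, and at least 1.41 times as many as the next among peaks at or above each list's median −log10 p, which argues against weak peaks. Extra copies of the chromosome could not be decided: blocked height on chromosome 15 was 1.21 (Mef2Da1-BLOCK) and 1.18 (Mef2Da2-BLOCK) times the median of the others, around the bound of 1.2 set before, while the isoforms' own mean heights there were 1.03 and 0.98 times that of the others. Mean blocked height was highest on chromosome 15, at 22.5 (Mef2Da1-BLOCK) and 14.6 (Mef2Da2-BLOCK) against at most 20.4 and 13.4 elsewhere. Blocked height also followed peak density across the 19 chromosomes. The Spearman correlation was 0.63 and 0.66 (permutation p = 0.0058 and 0.0024). The Pearson correlation was 0.84 and 0.82 (permutation p = 0.0001 for both, the smallest that 10000 permutations can give). Benjamini-Hochberg adjusted p was at most 0.0058 over the 4 relations. Without the 2 chromosomes farthest from the median, the Pearson correlation was 0.63 and 0.64. Extra copies could raise blocked height and peak density together, so this relation cannot decide for or against them. For dense clusters, the planned test met its prediction. After merging within 100 kb, chromosome 15 had 1.79 and 1.93 clusters per Mb against 2.02 and 2.01 on chromosome 11, a lower ratio of 0.884. Peaks placed at random gave 3.46 and 3.57 against at most 3.17 elsewhere. Real peaks formed fewer clusters per Mb than random ones on each chromosome, for example 2.02 against 3.17 on chromosome 11 for Mef2Da1. Random placement lacked this clumping, so it cannot show whether merging forces that outcome on a denser chromosome. The measures added after it disagreed, the mean per 1 Mb window without the fullest 10% of windows being at least 1.18 times that of any other chromosome and the median window 4 against 5 for Mef2Da1 (ratio 0.8) and 6 against 5 for Mef2Da2, so clusters remain a possible explanation that is not settled.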
